A study of Homo sapiens with 18 samples.

How the data were processed

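RNA secondary structure was probed at 37 °C by PARS (parallel analysis of RNA structure) in GM12878, GM12891 and GM12892, established lymphoblastoid cell lines made from B cells with Epstein-Barr virus. In PARS, RNA is cut either by S1 nuclease, which cuts single-stranded bases, or by RNase V1, which cuts double-stranded or stacked bases, and the cut ends are sequenced. The series held 18 samples: 12 structure libraries, which form 6 preparations with an S1 and a V1 library each, and 6 AGO iCLIP samples. In 3 preparations, 1 for each line, poly(A)-selected RNA had been extracted with Trizol and renatured before cutting. The other 3 preparations were of rRNA-depleted GM12878 RNA from cells lysed in mild detergent and extracted with phenol: 2 replicates in which the RNA was left in its native, deproteinized state and 1 in which it was renatured afterwards. AGO iCLIP sequences the RNA crosslinked by UV light to Argonaute, the protein that carries microRNAs, and was done in 2 replicates per line.

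Per the labels, the authors aligned the structure reads with Bowtie2 and the iCLIP reads with Bowtie, versions not given, and named hg19 as the genome build. The deposited structure values are a score for each base of a transcript: the read number of a library multiplied by 1 factor and rounded to whole numbers, with library totals brought to nearly the same level within each RNA selection. The factor is not given. From the gaps between the whole numbers it was estimated at 0.845 to 1.507 per library, which would put the libraries at 107 to 214 M reads. Because these are estimates, no counting intervals were computed. Each library held 154575876 bases of 74211 transcripts. The transcripts were 33371 with NM and 6674 with NR identifiers (coding and noncoding RefSeq), 19792 Ensembl and 14281 assembled (TCONS) transcripts and 93 others. A deposited table of transcript scores covered 65535 transcripts, and all 786420 of its 786420 entries equalled the sum of the per-base scores exactly. The deposited AGO peaks are intervals in transcript coordinates, 1 list for each line, without strand, score or replicate, and carry no other unit. How the peaks were called is not stated. The last 49 bases of transcripts carried 0% of the signal and were left out of per-base means.

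Of the 40045 RefSeq transcripts, 38639 were paired with a gene symbol, which gave 22980 genes. For each gene the transcript with the most S1 and V1 signal over the 6 preparations was used. XIST, Y-linked genes, immunoglobulin, T cell receptor and HLA genes (125 in all) were left out, and 22855 genes were kept. No transcript annotation or genome sequence was at hand, so the comparisons of untranslated and coding regions, of codon positions and of start and stop codons were not made, and AGO peaks were not restricted to 3' untranslated regions. Chromosome positions and exons are likewise not given. In their place, position along the transcript and periodicity of PARS without a reading frame were measured, which was decided after the data were examined.

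PARS of a gene was log2 of the summed V1 score plus 1 over the summed S1 score plus 1, centred on the median of the preparation. Higher values stand for more double-stranded signal. Native and renatured RNA were compared with limma 3.58.1 (empirical Bayes with a trend) in R 4.3.3 over the 1725 genes with a mean score of at least 1 per base in the 3 rRNA-depleted preparations, with 1 residual degree of freedom. Each preparation gives 1 PARS value, so S1 and V1 libraries are paired within the preparation, which is the block. The RNA selections were compared with limma on log2 of the gene score plus 1, with 4 residual degrees of freedom, over the 12715 genes with a mean of at least 100 over the 6 preparations. Methods for counts were not used because the values are scaled scores. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. All tests were two-sided.

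The 24 gene lists were written before the data were examined. They cover structured and long noncoding RNA, histones, ribosomal proteins, oxidative phosphorylation, other housekeeping and regulatory groups, B cell genes, and markers of T or NK cells, monocytes, fibroblasts or epithelia, and erythroid cells. Lists with at least 5 tested genes were tested with camera (preset correlation 0.01). It asks whether the t statistics of a list lie higher or lower than those of other genes. An estimated correlation and fry were the alternatives. Some ribosomal protein pseudogenes entered that list by their symbol. The rule for naming genes was also fixed before the data were examined. It takes the 10 largest rises and 10 largest falls among called genes whose preparations did not overlap between groups. Where fewer than 10 passed, genes with the smallest p filled the places as values only. The 2 to 4 members of each list with the largest change, and FTH1, FTL, TFRC, GPX4, MALAT1, NEAT1, RN7SK, RMRP, RPPH1 and H4C3 where measured, were added. RN7SK was not among the tested genes. For the lines the rule takes the 10 largest differences per pair in the 25% of genes with the highest signal, and for AGO the 10 genes with the most peaks in all 3 lines.

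The lines have 1 preparation each, so differences in PARS above 1 between 2 lines were counted without a test and set beside the same count between the native replicates. AGO peaks were compared by overlap of at least 1 base on the same transcript and set beside 100 random placements of the windows on their transcripts. For PARS at peaks, windows on 1 transcript per gene were used, the mean of per-base log2((V1 + 1)/(S1 + 1)) within a window was set against the 50 nt on each side, and signs were permuted 100000 times over windows, with a smallest p of 1e-05. The transcript of a gene was chosen over the 3 lists together, a choice made after first values had been seen, and the choice per list was kept as an alternative. Gene lists were also set against 10000 random lists matched on signal in 20 bins, which was decided after the data were examined. For periodicity, the power of PARS at 3 nt relative to nearby frequencies was taken in consecutive segments of 300 nt of transcripts of at least 649 nt with a mean score of at least 5 per base, and tested with an exact sign-flip permutation over the 6 preparations, for which the smallest possible p is 0.03125.

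The alternatives fixed before the data were examined changed the pseudocount, the minimum signal, centring, the pairing, the ratio of sums, the trend, the libraries used, each preparation in turn, the overlap and the flanks. Counting bases with signal in place of summed score, median-centred log2 values and several comparisons of windows were added after the data were examined. Planted changes were tested on simulated data. In the native comparison 15% of genes changed by 2 (log2) and 84% of those changed by 4 were recovered. The simulated noise had the SD between native replicates in all genes and preparations, so these shares may be too high for the measured data. In the comparison of RNA selections 3% of those changed by 1 and 41% of those changed by 3 were recovered. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for all other steps, and matplotlib 3.10.9 for plots.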

Results

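The series measured RNA secondary structure and AGO binding in the human lymphoblastoid lines GM12878, GM12891 and GM12892. PARS was measured in 3 preparations of renatured poly(A) RNA, 1 for each line, and in 3 preparations of rRNA-depleted GM12878 RNA, 2 native and 1 renatured. AGO iCLIP had 2 replicates per line, and the deposited peaks are 1 list per line that names no replicate. Library totals, in scaled score, lay between 185694828 and 187909983 in poly(A) RNA and between 161869359 and 162042333 in rRNA-depleted RNA. These near-equal totals spread over very different numbers of bases. In poly(A) RNA, 16364712 to 20856789 bases carried S1 signal and 6516643 to 8557444 carried V1 signal. In rRNA-depleted RNA, 190671 to 757322 bases carried S1 signal and 378569 to 1187579 carried V1 signal. In the poly(A) libraries 428119 to 649509 bases held 50% of the signal, and in the rRNA-depleted libraries 86 to 471 bases did. Precision per transcript was therefore lower in rRNA-depleted RNA than the totals show.

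**Figure D1:**
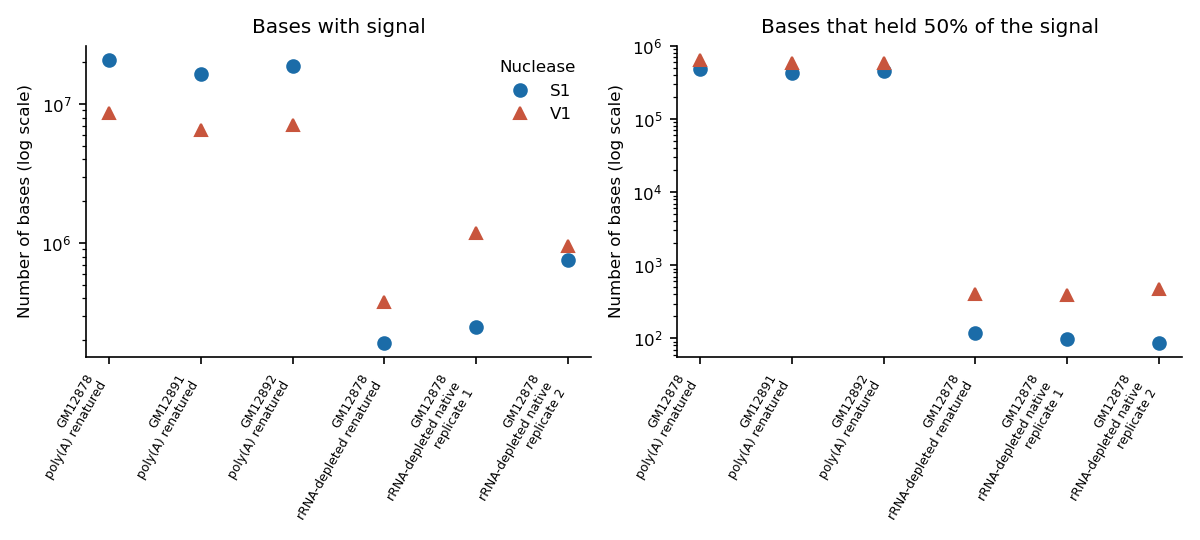
Number of bases with signal (left) and number of bases that held 50% of the signal (right), both on log scales, in the S1 and V1 library of each of the 6 preparations. The rRNA-depleted libraries held 50% of their signal on 86 to 471 bases and the poly(A) libraries on 428119 to 649509.

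Native and renatured RNA of GM12878 were compared to ask whether RNA folded in the cell differs in structure from RNA folded again after extraction. PARS of no gene differed between the states past the threshold: limma called 0 of 1725 genes, and 217 had an unadjusted p under 0.05. The differences with the smallest p, given as values only, were found in box C/D snoRNAs, which guide methylation of ribosomal RNA, and in short mRNAs. SNORD36A had a native minus renatured PARS of 7.11 ± 0.59 (SE, log2, 2 native preparations and 1 renatured), SNORD28 one of 6.26 ± 0.63 and SNORD70 one of 4.16 ± 0.53, while SNORD26 had one of -5.38 ± 0.54. Among mRNAs, NSMCE1, a subunit of the SMC5/6 complex, had a difference of -7.40 ± 0.66, POLR1H, an RNA polymerase I subunit, one of -6.50 ± 0.67, and CFAP68 one of -7.37 ± 0.93. EMC3, part of the ER membrane protein complex, had one of 4.87 ± 0.57. The noncoding PITPNA-AS1 and the pseudogene NACA4P had differences of -5.34 and -4.13. The adjusted p was 0.221 for all of these. In each of these genes the renatured preparation lay farther from 0 than the native replicates: centred PARS of SNORD36A was -7.62 after renaturing and -0.57 and -0.46 in the native replicates, and that of NSMCE1 was 6.15, -1.62 and -0.87. With 1 renatured preparation, the SE and p of this comparison rest on the spread between the native replicates, moderated across genes. They hold no measure of how renatured preparations vary. The values also rest on few bases. SNORD36A had 8 S1 and 3 V1 bases with signal in renatured RNA, and NSMCE1 had 8 and 28. On the number of bases with signal, the differences were 0.72 for SNORD36A and -0.81 for NSMCE1, that of NACA4P was -0.09, and that of SNORD70 turned to -1.19.

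Noncoding RNAs and mRNAs chosen in advance had smaller values. RPPH1, the RNA of RNase P, had a native minus renatured PARS of 2.65 ± 0.68 (SE, adjusted p = 0.305) and RMRP, the RNA of RNase MRP, one of 1.78 ± 1.32 (adjusted p = 0.610). The iron-regulated FTH1, FTL and TFRC had differences of -0.18, -0.28 and -0.28, the selenoprotein GPX4 one of -0.23, the nuclear RNA MALAT1 one of 0.29 and the histone H4C3 one of 0.02. Across genes, centred PARS of the native replicates correlated with Pearson's r = 0.589 (Spearman's rho = 0.621), and that of native replicates 1 and 2 with renatured RNA with r = 0.525 (rho = 0.542) and r = 0.478 (rho = 0.510). Genes are not independent replicates, and the renatured preparation had the fewest bases with signal. Without pairing S1 and V1 libraries in the block, 0 genes passed and 280 had an unadjusted p under 0.05. A minimum of 0.2 per base gave 216 called genes, a minimum of 5 gave 32 and no centring gave 74. Counting bases with signal, added after the data were examined, gave 3: EMC3 (1.97), PLGRKT (-2.10) and SDHAF3 (-1.94), which were named after their values were seen. With 1 residual degree of freedom, 15% of planted differences of 2 were recovered, so differences of that size were mostly not detectable. The simulated noise was alike in all genes and preparations. In the measured data larger differences, such as 7.11 in SNORD36A, did not pass either.

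**Figure D2:**
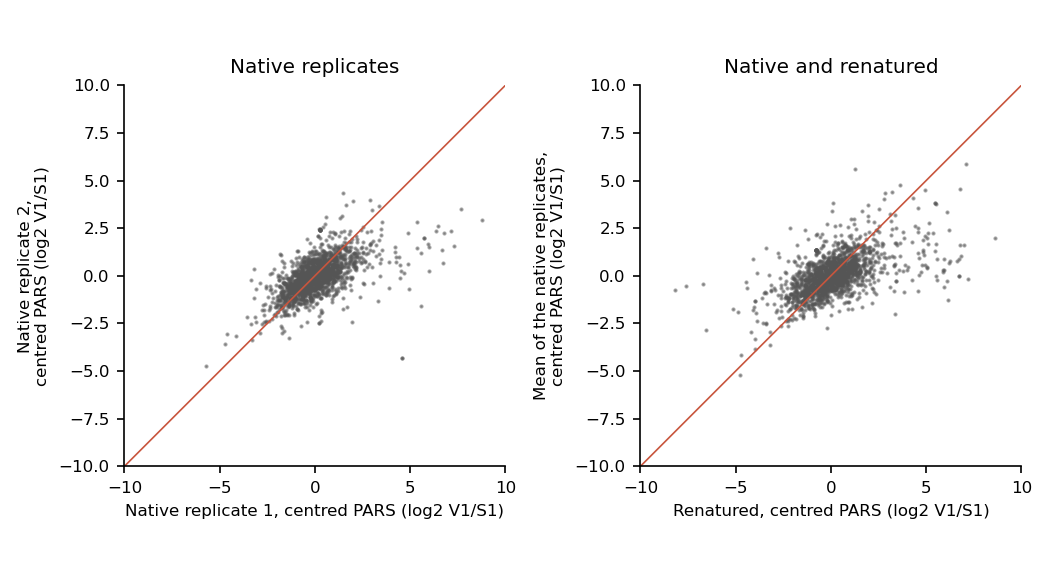
Centred PARS (log2 V1/S1) of the 1725 tested genes in native replicate 1 against native replicate 2 (left) and in renatured RNA against the mean of the native replicates (right), with the line of equality. Each point is a gene. Across genes r was 0.589 between the native replicates.

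Cytosolic ribosomal protein mRNAs were the only gene list with a call in this comparison, and the call depended on the measure. Of its 85 tested members 67 had a lower PARS in native than in renatured RNA, with a median of -0.40 (camera adjusted p = 0.0162). With an estimated correlation the adjusted p was 0.957, and with fry, which asks whether the list moves one way, it was 0.847. No member passed the test singly, nor when adjusted over the list alone. RPS16 had a difference of -1.67, RPS19 one of -1.27, RPS29 one of -1.26 and RPL7A one of 1.22. The 66 nuclear-encoded oxidative phosphorylation mRNAs had a median of -0.27 (adjusted p = 0.466), with NDUFA8 at -5.65, NDUFA7 at -5.50 and NDUFA11 at -4.63. Structured small noncoding RNAs had a median of 0.50 over 16 genes (adjusted p = 0.385), and 62 replication-dependent histone mRNAs, which end in a stem-loop and carry no poly(A) tail, had one of 0.19 (adjusted p = 0.820). With the mean of per-base log ratios both of these lists had an adjusted p of 0.00146 and medians of 0.42 and 0.47, while ribosomal proteins had an adjusted p of 0.658. Counting bases with signal, added after the data were examined, histones were called instead (median 0.31, adjusted p = 5.66e-05), and ribosomal proteins had a median of -0.08 (adjusted p = 0.996). The other 11 tested lists had adjusted p between 0.820 and 0.951, and for 4 of them median and mean differed in sign. Adjusted over the list alone, 2 selenoprotein mRNAs passed, GPX1 (-3.30) and SELENOS (2.11), as did the interferon-stimulated ISG20 (-4.42) and the single tested T or NK cell gene, LCK (-2.15).

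Poly(A) and rRNA-depleted RNA were compared to see which RNAs the 2 selections hold. The 3 poly(A) preparations came from 3 lines, were renatured and were extracted with Trizol, and the 3 rRNA-depleted ones came from GM12878 alone, by another lysis, with 2 of them native, so lysis cannot be separated from selection. As deposited, the log2 score over all genes had a median change of -3.93 from poly(A) to rRNA-depleted RNA (-3.94 with GM12878 only and -4.13 with renatured RNA only), so changes are given both as deposited and after each preparation was centred on its median, which was added after the data were examined. Small noncoding RNAs without a poly(A) tail stood highest in rRNA-depleted RNA. VTRNA1-2, a vault RNA, rose by 12.53 ± 1.38 (SE, log2, 3 against 3 preparations, adjusted p = 8.63e-05) as deposited and by 16.17 centred. The H/ACA snoRNAs SNORA74A and SNORA74B rose by 10.83 ± 0.42 and 10.50 ± 0.39, the Cajal body RNA SCARNA13 by 9.83 ± 0.35, the box C/D snoRNA SNORD17 by 9.63 ± 0.20 and RNU12, the U12 snRNA of the minor spliceosome, by 9.57 ± 0.28. The microRNA loci MIR4521 and MIR1248 rose by 11.25 ± 0.99 and 10.05 ± 0.34, and MIRLET7A1, listed at 0 in all 3 poly(A) preparations, had a mean score of 1173 in rRNA-depleted RNA. MIR4521 had at most 4 bases with signal and MIRLET7A1 at most 5.

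Long mRNAs stood lowest in rRNA-depleted RNA. TRIM56, a ubiquitin ligase, fell as deposited (-12.86 ± 0.89, SE, log2, 3 against 3 preparations, adjusted p = 9.35e-06) and centred (-9.21), from a mean score of 9347 to 0.333. TNRC18 fell (-12.62 ± 1.01), as did PLEC, the cytoskeletal linker plectin (-11.97 ± 0.84), RAI1 (-11.84 ± 1.05) and PRR12 (-11.80 ± 1.12). RAD54L2 (-11.54 ± 1.01), the tyrosine kinase gene TNK2 (-11.49 ± 1.07) and PKD1, which encodes polycystin-1 (-11.47 ± 0.82), also fell. The noncoding LINC01001 fell (-11.62 ± 0.95), and LINC01002 was listed at 0 in all 3 rRNA-depleted preparations against a mean score of 6241 in poly(A) RNA. The same 10 genes also fell on median-centred values. Among genes fixed in advance, RPPH1 rose by 6.69 ± 0.68, RMRP by 4.38 ± 0.18 and H4C3 by 4.15 ± 0.42. FTH1 fell as deposited (-1.43 ± 0.17) and rose centred (2.21), and FTL likewise fell (-1.83 ± 0.18) and rose (1.81). The nuclear RNA NEAT1 fell as deposited (-7.09 ± 0.31) and centred (-3.44). MALAT1 (-4.11), TFRC (-4.13) and GPX4 (-3.15) fell as deposited. Centred, TFRC fell (-0.48, adjusted p = 0.0212), although it turned to 0.85 on bases with signal, and MALAT1 at -0.47 and GPX4 at 0.49 did not pass.

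In all, 325 genes rose and 11443 fell as deposited, of 12715 tested. Centred, 2983 rose and 2659 fell, and 5257 of these 5642 genes were also called as deposited, in either direction. Only 325 rose as deposited, so most genes that rose centred and were called under both scalings fell as deposited. Counting bases with signal, also centred and added after the data were examined, 4344 rose and 3432 fell. With GM12878 alone on the poly(A) side, which leaves 1 preparation there, the median change as deposited was -3.94. The poly(A) and rRNA-depleted groups share only 1 replicate number, so no paired fit or block was possible.

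Histone and structured noncoding RNAs rose as groups in rRNA-depleted RNA. Of 66 replication-dependent histone genes 61 rose, with a median of 4.19 as deposited and 7.83 centred (camera adjusted p = 7.23e-209; 0.0205 with an estimated correlation), led by H3C7 (6.92), H2AC21 (6.85), H2BC3 (6.54) and H1-5 (6.41). H2AC25 was the only one that fell (-2.69), a gene named after its value was seen. Of 18 structured small noncoding RNAs 16 rose, with a median of 6.81 as deposited and 10.45 centred (adjusted p = 2.99e-79; 0.00068 with an estimated correlation), among them SCARNA5 (9.30). SCARNA17 fell (-3.90), and TERC, the telomerase RNA, had a change of 0.32 (adjusted p = 0.681); both were named after their values were seen. Centred, 64 histones and 17 structured RNAs rose, and the adjusted p with an estimated correlation was 0.130 and 0.121. Adjusted over the list alone, 62 histones and 17 structured RNAs were called as deposited.

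Ribosomal protein, oxidative phosphorylation, proteasome, translation factor and long noncoding RNA lists had medians of opposite sign under the 2 scalings. Of 91 ribosomal protein genes 75 fell and 2 rose (RPS23, 0.76, and RPS27A, 0.54) as deposited, with a median of -1.16 although camera placed the list above other genes (adjusted p = 0.198). Centred, 83 rose and 2 fell, with a median of 2.49 (adjusted p = 6.39e-34; 0.0364 with an estimated correlation). The members with the largest change as deposited were pseudogenes, RPL32P3 (-6.71) and RPL13P5 (-6.50), besides RPL7L1 (-4.73); RPS16P5 was listed at 0 in rRNA-depleted RNA. Of 79 oxidative phosphorylation genes 67 fell as deposited, with a median of -1.62 (adjusted p = 0.820), and 64 rose centred, with a median of 2.02 (adjusted p = 9.13e-20; 0.124 with an estimated correlation). SDHA (-4.84) and NDUFV1 (-4.44) fell as deposited. All 38 proteasome genes fell as deposited (adjusted p = 0.00821; 0.563 with an estimated correlation) and 25 rose centred (adjusted p = 1.9e-05; 0.201 with an estimated correlation); PSMD3 fell as deposited (-5.92) and centred (-2.28), but had a change of 0.07 on bases with signal. All 59 translation factor genes fell as deposited (adjusted p = 0.000284; 0.503 with an estimated correlation), among them EIF4G1 (-8.23) and EIF3A (-6.27), and centred 24 rose and 12 fell (adjusted p = 0.0154 upward; 0.130 with an estimated correlation). Long noncoding RNAs had 18 that fell and 3 that rose as deposited, SNHG7 (4.79), SNHG6 (0.79) and HOTAIR (8.71), with a median of -1.60 although camera placed the list above other genes (adjusted p = 0.00628; 0.503 with an estimated correlation). Centred, 15 rose and 2 fell, with a median of 2.04 (adjusted p = 0.000331; 0.124 with an estimated correlation). HOTAIR, a noncoding RNA of the HOXC locus, had a score of 1336401 in GM12878 poly(A) RNA, 1322 in GM12891 and 119 in GM12892, so its change of 8.71 comes mostly from the lines, and within GM12878 the log2 ratio of the rRNA-depleted mean to poly(A) RNA was 0.93.

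The AGO and microRNA machinery, a list of long mRNAs, fell under both scalings. All 16 of its genes fell as deposited, with a median of -4.55, and 10 fell and 1 rose centred, with a median of -0.91 (adjusted p = 0.0240 and 0.0150; 0.503 and 0.130 with an estimated correlation). After the change of coding transcripts of like length was taken off, the centred median was -0.15 and 8 of 16 genes lay above 0, with no test made. TNRC6A fell as deposited (-8.43) and centred (-4.79), as did TNRC6B (-6.80 and -3.16) and TNRC6C (-7.34 and -3.70). Other lists fell as deposited and had no call centred. In the B cell list 29 of 30 genes fell as deposited (adjusted p = 0.00277; 0.503 with an estimated correlation), led by PAX5 (-10.19), and VPREB3 (-1.71) did not pass; centred, 4 rose and 7 fell (adjusted p = 0.364). All 43 splicing factors (adjusted p = 8.09e-06; HNRNPUL2, -7.95), 28 heat shock genes (0.000202; HSPA1A, -7.16), 17 glycolysis genes (0.000416; HK2, -6.96), 22 G2/M genes (0.00291; MKI67, -7.86), 31 B cell surface genes (0.00441; SLC7A5, -7.09) and 32 interferon-stimulated genes (0.0338; OAS3, -9.01) fell as deposited. The centred adjusted p of these 6 lists lay between 0.589 and 0.929. Their adjusted p with an estimated correlation was 0.503 for each as deposited. Their medians as deposited lay between -3.76 and -3.45, above the median of -3.93 over all genes. Because camera compares t statistics, these calls do not mean larger falls than in other genes. The same holds for the proteasome and translation factor lists, with medians of -2.58 and -3.23 as deposited. Zinc finger genes (405 tested, 382 fell, adjusted p = 0.343), immediate early genes (33, 32 fell, 0.131), selenoproteins (16, all fell, 0.539) and iron-responsive genes (7, all fell, 0.539) had no call as deposited, and their centred medians were -0.91, -0.25, 0.46 and -0.48 (adjusted p = 0.0894, 0.558, 0.142 and 0.619). ZNF324 (-9.52), JUN (-9.32) and SELENON (-8.29) fell as deposited, and ZNF70 was listed at 0 in rRNA-depleted RNA against a mean score of 1293 in poly(A) RNA. For zinc finger genes, ribosomal proteins, oxidative phosphorylation, long noncoding RNA and T or NK cell genes, camera pointed up as deposited while median and mean were negative. Markers of other cells were scarce. Of T or NK cell genes 7 of 9 tested fell as deposited (adjusted p = 0.168), as did all 6 fibroblast or epithelial genes (0.662) and all 3 monocyte genes (too few to test, CSF1R at -8.18), and no erythroid gene of the lists was tested. Mitochondrially encoded genes of the lists were not tested either. None was among the genes with a symbol, so this does not show that their RNA was scarce.

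**Figure D3:**
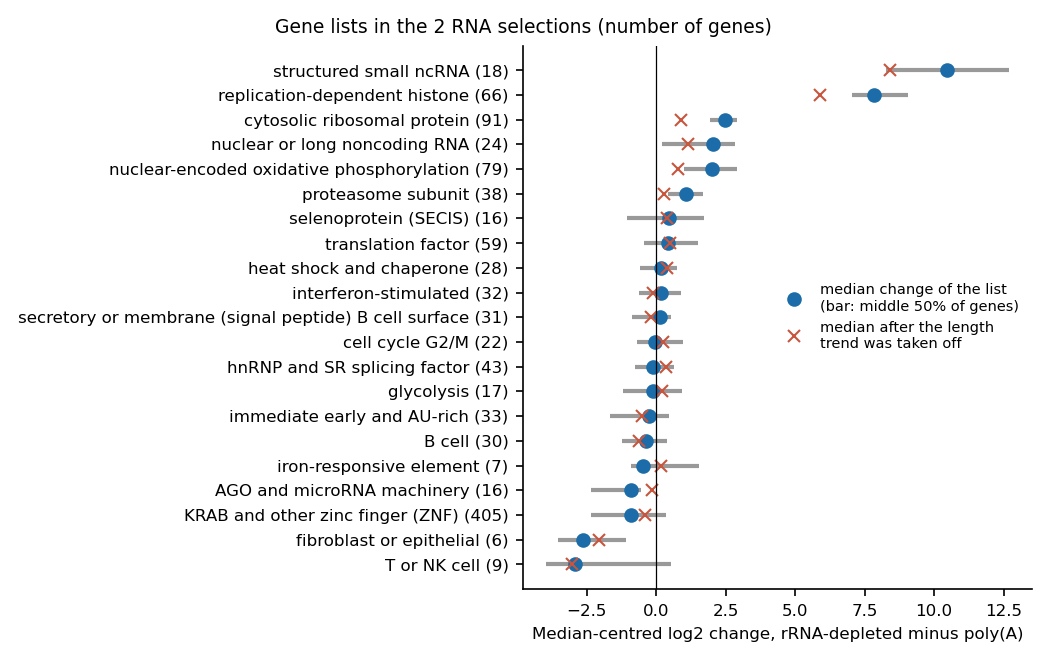
Median-centred log2 change from poly(A) to rRNA-depleted RNA of each gene list (points, medians; bars, the middle 50% of genes; number of genes in brackets) and the median after the change of coding transcripts of like length was taken off (crosses). For transcripts shorter than 719 nt, the change of the shortest group of coding transcripts was taken off. Histones (7.83) and structured noncoding RNAs (10.45) lay highest. As deposited, every list lay lower by the same amount, and lists near 0 had negative medians.

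The 3 lines were compared in poly(A) RNA to find genes whose RNA differs in structure between them. Each line had 1 preparation, so sizes are given without a test. Few genes differed: centred PARS differed by more than 1 (log2) in 96 of 7999 genes between GM12878 and GM12891, in 118 of 7912 between GM12878 and GM12892 and in 74 of 7987 between GM12891 and GM12892. Between the native replicates of GM12878, the only replicates of 1 state and with signal on far fewer bases, 481 of 1973 genes (24.4%) differed by as much, so the differences between lines were fewer than those between these replicates. The genes with the largest differences were nearly all snoRNAs. SNORD5 had a PARS higher by 3.27 in GM12878 than in GM12891 and by 3.48 than in GM12892, SNORD45C by 2.88 and 3.66, SNORD104 by 2.46 and 3.33 and SNORD111B by 2.30 and 3.44. SNORA84 was higher by 2.91 and SNORA3A by 2.59 in GM12878 than in GM12891, and SNORD11 by 3.23 and SNORD31 by 3.18 in GM12878 than in GM12892. Between GM12891 and GM12892, SNORD95 differed by 2.69, SNORD103A and SNORD103B, with identical values, by 2.56, and RNU11, the U11 snRNA, by 2.09. These RNAs are mostly lost in poly(A) selection. On the number of bases with signal the differences shrank to 0.36 and 0.42 for SNORD104 and turned to -0.48 and -0.42 for SNORD5. The sign also turned for SNORD111B (-0.71 and -0.67), SNORD31 (-0.74) and SNORD95 (-0.43), and SNORD45C had -0.02 and 0.15. SNORA84 (0.50), SNORA3A (0.49) and SNORD11 (0.75) kept their sign, and SNORD103A and RNU11 had 0.01 each. Across genes r between lines was 0.856, 0.783 and 0.871 (rho 0.886, 0.855 and 0.880), against 0.582 (rho 0.611) between the native replicates, and genes are not independent replicates.

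Several gene groups lay on the same side of the median PARS in all 3 lines. This description was added after the data were examined, and lists are set against random lists of the same size and like signal. Ribosomal protein mRNAs had the lowest PARS of the large groups, with list medians of -0.44, -0.49 and -0.54 in GM12878, GM12891 and GM12892 over 87 genes, of which 73 lay below the median of all genes in every line. Oxidative phosphorylation mRNAs had medians of -0.26, -0.30 and -0.39 over 79 genes and zinc finger mRNAs of -0.22, -0.29 and -0.26 over 126 genes. For these 3 lists, 0% of the 10000 random lists lay lower in any line. The random lists were not matched on transcript length, so length cannot be told apart from the group. Over the genes tested between RNA selections, median length was 710 nt for ribosomal proteins and 804 nt for oxidative phosphorylation. It was 3234 nt for zinc finger genes. Selenoprotein mRNAs, which hold a stem-loop for inserting selenocysteine, had medians of -0.42, -0.37 and -0.28, and proteasome mRNAs of -0.24, -0.27 and -0.25. Immediate early and AU-rich mRNAs had the highest PARS, with medians of 0.33, 0.32 and 0.32 over 26 genes, above 99.7% to 99.9% of random lists. Glycolysis mRNAs had medians of 0.17, 0.21 and 0.20 over 17 genes, above 97.7% to 99.3% of random lists. Structured small noncoding RNAs varied between lines, at 0.03, -0.83 and -0.57 over 10 genes. Long noncoding RNAs lay at -0.28, -0.30 and -0.22 and replication-dependent histones at -0.18, -0.13 and -0.05. The AGO and microRNA machinery lay at 0.17, 0.20 and 0.23 and B cell genes at 0.09, 0.15 and 0.06. Cell cycle, heat shock, splicing factor, interferon-stimulated, B cell surface and translation factor lists lay between -0.21 and 0.12, inside 8.35% to 93.5% of their random lists. Single genes with high PARS in all lines included POTEF, a relative of the actin genes, with a mean of 2.70 ± 0.24 (SD, n = 3 lines), and SNORD76 with 2.25 ± 0.95; SNORD95 had -4.28 ± 1.43.

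**Figure D4:**
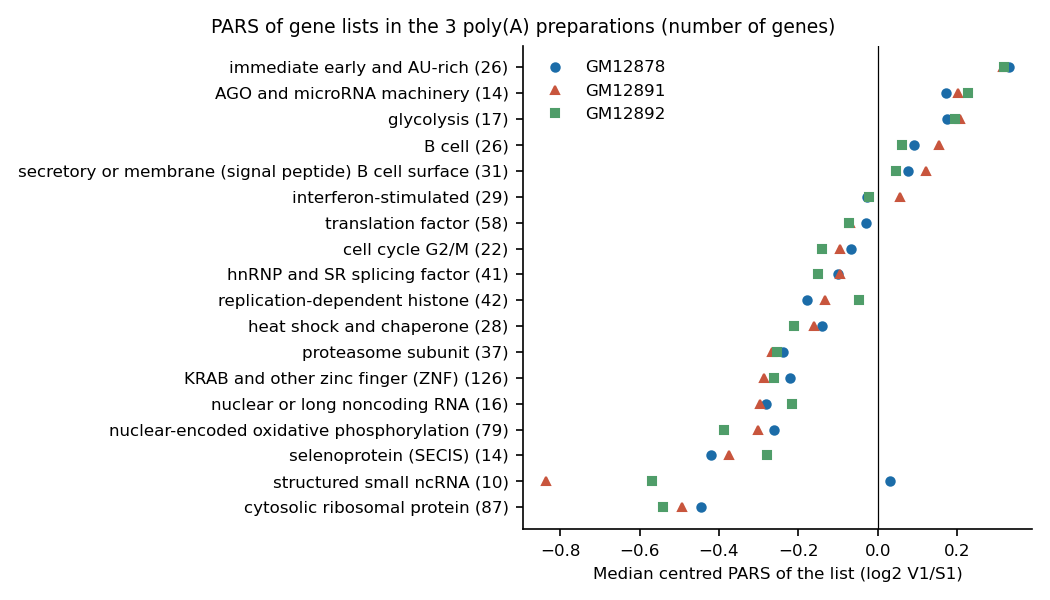
Median centred PARS (log2 V1/S1) of each gene list in the poly(A) preparations of GM12878, GM12891 and GM12892 (number of genes in brackets). Ribosomal protein mRNAs lay at -0.44, -0.49 and -0.54 and immediate early and AU-rich mRNAs at 0.33, 0.32 and 0.32.

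Coding transcripts carried a 3-nt rhythm in PARS, and the same measure was lower in noncoding transcripts. The power of PARS at a period of 3 nt relative to nearby periods, as log2, was 0.487 ± 0.122 (SD, n = 6 preparations) in coding (NM) transcripts and above 0 in 6 of 6 preparations, with an exact sign-flip permutation p = 0.03125, the smallest possible. It exceeded that of noncoding (NR) transcripts by 0.188 ± 0.063, also in 6 of 6 preparations (exact sign-flip p = 0.03125). The value in noncoding transcripts was itself above 0 in every preparation, at 0.134 to 0.391. In renatured rRNA-depleted RNA it was higher at 5 nt (0.239) than at 3 nt (0.134). In the other preparations it was highest at 3 nt, with at most 0.173 at 4 nt and 0.188 at 5 nt. Whether noncoding transcripts carry a rhythm is thus not settled. With S1 signal alone, added after the data were examined, the excess was 0.094 ± 0.220 and did not pass (exact p = 0.344). Noncoding transcripts numbered only 17 to 62 per preparation, and in native replicate 2 their median power ratio was higher than that of coding transcripts (1.405 against 1.250). At periods of 4 and 5 nt the value in coding transcripts was far smaller, 0.031 and 0.063, although also above 0 in 6 of 6 preparations. Both had the same exact sign-flip p of 0.03125, so the test against 0 does not set 3 nt apart. The sizes do: the lowest value at 3 nt was 0.257, and the highest at 4 and 5 nt were 0.136 and 0.145. The preparations share genes and most are of GM12878, so they are not independent samples. The reading frame was not at hand, so which codon position was more double-stranded was not measured. PARS of the first decile of coding transcripts relative to the whole lay between 0.102 and 0.129 in the 3 poly(A) preparations and between -0.302 and -0.0883 in the 3 rRNA-depleted ones, and that of the last decile between 0.0441 and 0.0605 and between -0.418 and 0.0725. For the first decile the signs differ between the selections, so a test over all 6 preparations decides nothing there. The choice of these measures was made after the data were examined.

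AGO peaks were compared between lines to ask how far AGO binding is shared. The lists held 4370 peaks in GM12878, 6755 in GM12891 and 3693 in GM12892, of which 91.9%, 92.8% and 90.9% lay on coding transcripts. Peaks were windows of 50 nt on a grid of 25 nt. They lay on 2344, 3179 and 1863 transcripts, with 1429, 1889 and 1088 gene symbols. The lists thus hold several transcripts of a gene, and a site in their common sequence can count more than once. The peak numbers and shares here are over all listed transcripts. Of GM12878 peaks 26.2% overlapped a GM12891 peak and 17.7% a GM12892 peak, of GM12891 peaks 16.9% and 15.6% overlapped GM12878 and GM12892 peaks, and of GM12892 peaks 21.0% and 28.5% overlapped GM12878 and GM12891 peaks. Random placement on the same transcripts gave 2.15% to 3.95%. Replicates are not separate in the lists, so the overlap between replicates of 1 line, the yardstick for these shares, is unknown. Of 7758 genes with enough signal in every line, 380 had a peak in all 3 lists, against 29.7 expected from the sizes of the lists, and their median score per base was 5.48 against 3.26 in genes with no peak.

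The 10 genes with the most peaks in all 3 lines were taken by the fixed rule. IRF4, a transcription factor of activated B cells and plasma cells, TP53INP1, a gene induced by p53, and the kinase gene UHMK1 each had 4 peaks found in all 3 lines. AKAP11, CDKN1A, which encodes the cell cycle inhibitor p21, the phosphatase gene DUSP5, the chaperone gene HSPA8, RNF19A and XIAP, an inhibitor of apoptosis, had 3 each. ACTB had 2, a number shared with other genes, and was taken by alphabetical order. Counted from 1 at the 5' end of the transcript, a peak at 1501 to 1550 of the 5324-nt IRF4 transcript and one at 776 to 825 of the 2159-nt CDKN1A transcript were identical in the 3 lists. IRF4 had 13, 9 and 12 peaks and CDKN1A 5, 5 and 3 in GM12878, GM12891 and GM12892. Of 335 genes with peaks in each list on the chosen transcript, 213 had 1 or more shared by all.

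Some gene groups held more or fewer genes with AGO peaks in all 3 lists than random lists of like signal, a comparison added after the data were examined. The random lists were not matched on transcript length, so length cannot be told apart from the group here. Median length was 5509 nt for the AGO and microRNA machinery and 804 nt for oxidative phosphorylation. It was 2366 nt for immediate early and 2423 nt for glycolysis genes, all over the genes tested between RNA selections. Of 26 immediate early and AU-rich genes 8 had such peaks against 1.5 expected (adjusted p = 0.0072): BTG1, DUSP2, JUND, MCL1, TNFAIP3, ZFP36, ZFP36L1 and ZFP36L2, several of which encode RNA-binding proteins or regulators of growth and cell death. Of 14 genes of the AGO and microRNA machinery 4 had them against 0.509 (adjusted p = 0.0192): CNOT1, DICER1, TNRC6A and TNRC6B. Of 17 glycolysis genes 6 had them against 1.59 (adjusted p = 0.0315): ALDOA, ENO1, GPI, LDHA, PFKP and PKM. None of 79 oxidative phosphorylation genes had them against 7.33 (adjusted p = 0.0072). The genes in these counts were named after their values were seen. Fisher's exact test without matching on signal also called 3 lists that matching did not: 10 of 58 translation factor genes (matched adjusted p = 0.143), 5 of 26 B cell genes (0.544), among them IRF4, CD74 and MS4A1, and 5 of 28 heat shock genes (0.698). It did not call oxidative phosphorylation (adjusted p = 0.0853). The other 11 lists tested had matched adjusted p between 0.698 and 1.

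PARS at AGO peaks was compared with the flanks to ask whether bound sites are more single-stranded. In poly(A) RNA of the same line, PARS within peaks was lower than in the 50 nt on each side by a small amount in all 3 lines. The difference was -0.053 ± 0.014 (SE, 1874 windows, adjusted permutation p = 0.00013) in GM12878, -0.070 ± 0.011 (2953 windows, adjusted permutation p = 1.5e-05) in GM12891 and -0.072 ± 0.015 (1484 windows, adjusted permutation p = 1.5e-05) in GM12892. It was below 0 in 53.2%, 55.3% and 54.5% of windows. Against random windows of the same transcripts, added after the data were examined, it was lower (differences of -0.046 ± 0.019, -0.069 ± 0.016 and -0.075 ± 0.022, SE; adjusted permutation p = 0.0186, 6e-05 and 0.000675). In PARS of the native GM12878 replicates, which rests on only 297 to 722 windows, the difference did not pass. With the GM12878 list it was -0.00095 ± 0.027 and 0.017 ± 0.022 (SE, adjusted permutation p = 0.972 and 0.536), and with the other lists it lay between -0.012 and 0.024 (adjusted permutation p of 0.536 to 0.711). Windows are not independent replicates of a line.

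**Figure D5:**
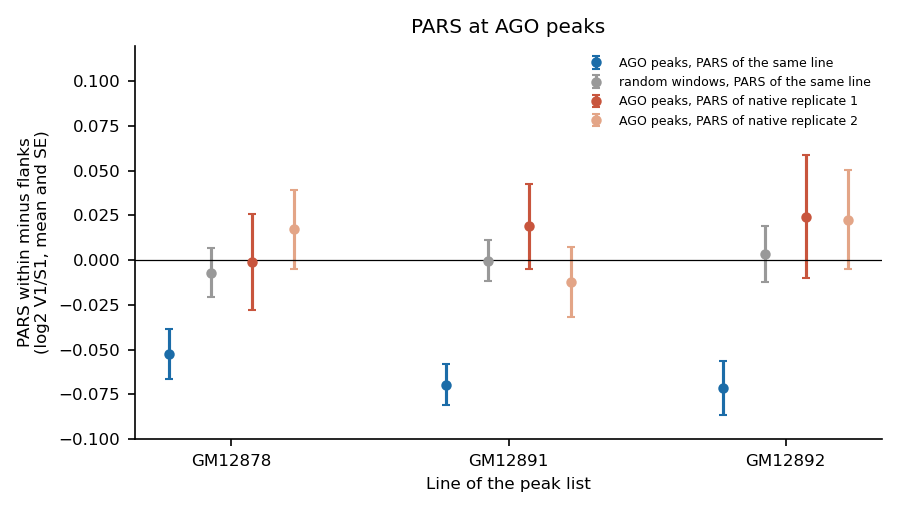
Mean PARS (log2 V1/S1) within windows minus that of the flanks, with its SE over windows, for the AGO peaks of each line. Peaks with PARS of the same line lay at -0.053, -0.070 and -0.072, random windows of the same transcripts between -0.007 and 0.004, and peaks with PARS of the native replicates between -0.012 and 0.024.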

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

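The tests of HOTAIR and the splits of the preparations were chosen after the results were seen, and those of bases and length were written before. The poly(A) and rRNA-depleted preparations differed in 2 measures in which every preparation of 1 group lay on one side of 0 and every preparation of the other group on the other side. The first is the log2 ratio of V1 to S1 bases with signal, at -1.29, -1.33 and -1.40 in poly(A) RNA of GM12878, GM12891 and GM12892 and at 0.99 (renatured), 2.25 and 0.33 (native replicates 1 and 2) in rRNA-depleted RNA. The second is PARS of the first decile of coding transcripts relative to the whole, at 0.102, 0.107 and 0.129 in poly(A) RNA and at -0.163, -0.302 and -0.0883 in rRNA-depleted RNA in the same order. Neither difference was tested. Another result stands out because it lies in data the comparisons of genes did not use: transcripts with Ensembl identifiers and no gene symbol took 10.2%, 9.98% and 10.2% of the signal in poly(A) RNA and 78.2%, 77.0% and 73.9% in rRNA-depleted RNA. One of them, 1558 nt long, took 8.61%, 8.44% and 10.7% of the rRNA-depleted signal, and the files do not give its gene.

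In the rRNA-depleted libraries 50% of the signal lay on few bases. A few abundant RNAs taking most of the score is argued against as the whole cause: at matched length and score, genes of poly(A) RNA had more bases with signal than those of rRNA-depleted RNA by a median ratio of at least 4.31 (13.3, 4.31 and 4.49 in the 3 preparations). Many copies of few cut molecules stays open. Of the V1 bases at 20 or more in native replicate 1, 50.4% stood at 0 in native replicate 2, past the bound set beforehand. The same share was 50.4% between the poly(A) V1 libraries of GM12891 and GM12892, which lack the pattern, so the V1 share cannot decide. Only S1 sets the rRNA-depleted libraries apart: 27.9% and 69.1% between native replicates against 0.444% and 0.425% between poly(A) libraries. The cell line is argued against, since 486046 (S1) and 649509 (V1) bases held 50% of the signal in GM12878 poly(A) RNA against 86 to 471 in rRNA-depleted RNA of the same line, and lysis and RNA selection stay open because they go with the groups.

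HOTAIR carried high signal in all 4 GM12878 preparations and little in the other lines. An ordinary polyadenylated RNA of the cells is argued against, since its change from poly(A) to rRNA-depleted GM12878 RNA lay at percentile 99.6 of 9766 coding transcripts. Activity of the HOXC cluster stays open: the highest of 9 HOXC genes, HOXC4, had a score of 2101, or 0.157% of HOTAIR, and HOXC4 had 1015 and 1676 in GM12891 and GM12892. An RNA added to the GM12878 material also stays open: 82.4% of the bases of HOTAIR carried signal, but the labels record no added RNA. A difference between the lines was not tested, because each has 1 preparation.

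Short transcripts stood relatively high in rRNA-depleted RNA, with Spearman's rho = -0.391 between length and centred change over 11534 coding transcripts. For histones the median centred change was 7.83. After the change of coding transcripts of like length was taken off it was 5.88, past the bound set beforehand. Histones had a median length of 461 nt, and below 719 nt the change of the shortest group, 2.03, was taken off. The length trend was not resolved there, so length stays open for histones. For ribosomal proteins the median went from 2.49 to 0.889 and for oxidative phosphorylation from 2.02 to 0.772. Both lie between the bounds set beforehand, so length may account for part of these 2 changes. The groups of like length include genes of these lists. The part that remains stays open, with selection, lysis and line. Of the 10 splits of the 6 preparations into 3 and 3, only 1, the real one, gave as many as 11768 called genes, and the highest of the others gave 0; 10 splits are too few for a share under 0.05.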

How the results depend on the processing

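Few transcripts of the rRNA-depleted libraries had signal on many bases, the native comparison had 1 residual degree of freedom and each line 1 poly(A) preparation, so depth and replicate number limit all comparisons. Median-centred values, bases with signal, a pseudocount of 10, the same window, parts of transcripts, random windows, the transcript chosen per list and the alternatives for periodicity were chosen after the data were examined.

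In the native comparison 0 genes were called, and 74 without centring, 32 with a minimum of 5 per base, 216 with a minimum of 0.2, 1 with the mean of per-base log ratios and 3 with bases with signal; 5 other alternatives kept 0, and the block changed no call. In 2 leave-one-out fits, without native replicate 1 or 2, values could not be tested, and the median absolute difference of 0.643 became 0.703 and 0.686. Between RNA selections 11768 genes were called, and 5642 median-centred, 7776 with bases with signal and 6774 with GM12878 only, while 11 alternatives stayed within 1.5 times, of which leaving out 1 preparation gave 11039 to 11760. Leaving a preparation of the same group out assumes that the others vary alike. Of native gene lists 1 was called, and 0 with an estimated correlation, 0 with fry, 2 with the mean of per-base log ratios and 1 with bases with signal, where histones took the place of ribosomal proteins. Of selection lists 13 were called, and 2 with an estimated correlation, 8 on median-centred values and 11 to 15 without 1 preparation each. Between lines 1.21% of genes differed on average, and 4.05% above a difference of 0.5, 1.95% with a minimum of 5 per base, 0.189% with the mean of per-base log ratios and 0.231% with bases with signal. Shared AGO peaks went from a mean of 21.0% to 13.96% with the same window. PARS at AGO peaks kept its sign and call in 8 alternatives per line, and with native replicates 1 and 2 it was -0.00095 and 0.017 in GM12878, 0.019 and -0.012 in GM12891 and 0.024 and 0.023 in GM12892. The excess of the power at 3 nt in coding over noncoding transcripts was 0.188, and 0.094 with S1 alone (exact permutation p = 0.344, n = 6). The smaller number of genes tested goes with the minimum of 5 per base; for all other changes the cause was not tested.

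Alternatives that need counts (TMM, DESeq2 and edgeR scalings) were not run because the values are scores. Those for regions, codon positions, start and stop codons, strand, peak score and 3' untranslated regions were not run because annotation, strand and score were not at hand. No paired analysis was possible between the RNA selections because the groups share only 1 replicate number.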

Other observations

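In the RNAs with the deepest signal, per-base PARS correlated more between the native replicates than with renatured rRNA-depleted RNA. This was looked at after the data were examined, in 79 RNAs with signal on many bases in all rRNA-depleted preparations, base by base. The median correlation of PARS along the RNA was 0.615 between the native replicates and 0.509 and 0.495 between native replicates 1 and 2 and renatured RNA, and the native pair had the highest value in 78 of 79 RNAs, SNHG10 being the exception. In RPPH1 the values were 0.765, 0.673 and 0.584, and in RMRP 0.698, 0.509 and 0.509. In the 52 of these RNAs that were also deep in GM12878 poly(A) RNA, which had been renatured, the native pair had a median of 0.604. Poly(A) RNA correlated with native replicates 1 and 2 at medians of 0.564 and 0.637 and with renatured rRNA-depleted RNA at 0.413, and it was closer to native replicate 2 than the native replicates were to each other in 37 of 52. Poly(A) RNA was closer to native replicate 1 than to renatured rRNA-depleted RNA in 52 of 52. Bases of an RNA are not independent, and there was 1 renatured rRNA-depleted preparation. That preparation had the fewest bases with signal among the rRNA-depleted ones (190671 for S1 and 378569 for V1). The correlations were not matched on this, so folding cannot be told apart from depth here.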
